A study of Homo sapiens with 2 samples.

How the data were processed

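ATAC-seq libraries were made from 2 cultures of GM12878, an established B lymphoblastoid line, with 50000 cells in each, per the labels and the series' design text. The labels put both libraries in 1 group. The authors deposited 1 list of regions for both, with the start, end, number and score of each region. The list carries no counts and no values per library, so the depth is unknown, the cultures could not be compared, and no interval that needs a depth is given. The submitters' processing notes name CASAVA 1.8.4, Trim Galore 0.3.3, BWA 0.7.13, Picard 1.92, SAMtools 0.1.19, bedtools 2.24.0 and MACS2 2.1.0 and the build hg19, without their roles. The list has no header, and whether the reads were shifted for the transposase is not given in the sources used here.

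The deposited score is a whole number per region, and neither a header nor a label names its scale. Its values fit the scaled score of the irreproducible discovery rate (IDR), 125 times the negative log2 of the IDR with a cap of 1000. On that scale an IDR of 0.05 gives 540, just under the lowest score of 541. The score was used to rank and filter regions within the list. Width was also compared by score, and the share of regions at the cap was compared among stain classes and among chromosomes. The name of the list also carries abbreviations that read as filters on mappability, mitochondrial DNA and a blacklist, which no label spells out. Tested on the list itself, 0 regions were mitochondrial. Regions are numbered in the order of position from 2 to 23983, with 370 numbers skipped. Of these, 230 fall across centromeric, variable or stalk bands, 71 elsewhere within a chromosome, and 69 between sequences.

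The list is in hg19, and the gene table at hand is of GRCh38.p14. Its coordinates were not used, and it served only to look up the 451 symbols of 23 gene lists, all of which it holds. The analyses fixed before the data were examined that need genes or sequence of hg19 were therefore not run. These are regions in promoters, protein-coding genes with an accessible promoter, the gene list comparisons, distal regions near B lineage genes, GC and CpG content, the share of genomic CpGs, the motifs, the width of promoter and distal regions, and the relation of regions per Mb to gene density. The rule for named genes, which rests on promoters, could name only regions and clusters: the 3 regions with the highest score, with ties broken by width, and the 5 clusters with most regions. In place of genes, regions were assigned by their midpoint to hg19 cytogenetic bands, taken with the sequence lengths from the R package circlize 0.4.16. The spread of regions per Mb over chromosomes took the place of the planned correlation. The comparisons of stains, single chromosomes, single bands, widths and scores, and intervals without regions were chosen after the data were examined, while the description of the list and the count of clusters had been planned.

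Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for plots. Densities are regions over Mb of band, with 95% percentile intervals from 10000 bootstrap draws of bands. Light bands were compared with each class of dark band by 100000 permutations of the stain among the bands of each chromosome. Each chromosome was compared with the others by 100000 permutations of bands among chromosomes, without centromeric, variable and stalk bands. These tests are two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Clusters join regions at most 12.5 kb apart, and those of 5 or more regions were counted. They were set against 100 random placements of the same widths without overlap. Regions in centromeric, variable and stalk bands kept their place, which leaves 1 cluster of 12 in every placement. Loci with a second copy in hg19 were compared with 10000 random windows of their length on the same chromosome. The windows left out the locus itself and centromeric, variable and stalk bands. Their bounds were rounded and set from general knowledge, as were the bands of the transcription factor genes in the closing section.

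The tests were tested on simulated data, with 23444 regions on chromosomes 1 to 22 and X. With no difference planted between light and darkest bands, 0 of 20 draws were called, and 20 of 20 were called with a planted ratio of 1.5, which was recovered as 1.51 on average. For chromosome 22, 0 of 20 draws were called with no ratio planted and 20 of 20 with a ratio of 0.5, recovered as 0.496. The draws for stains and chromosome 22 spread regions independently, whereas the regions of the list cluster. They therefore do not give the rate of false calls for clustered regions. After 200 clusters of 6 regions were planted, the number of clusters of 5 or more rose from 4 to 204. The alternatives tried were other joining distances, the score cap as a stricter threshold, subsets of chromosomes and bands, and the list without the loci that have a second copy.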

Results

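Accessible chromatin was measured in GM12878, a human B lymphoblastoid line that was established by transforming B lymphocytes with Epstein-Barr virus. The assay was ATAC-seq, in which a transposase cuts open DNA and tags it for sequencing. The 2 libraries came from separate cultures, with 50000 cells in each, and form 1 group, so no conditions were compared. The deposited result is 1 list of regions for both cultures, without values per culture. The depth of each library is therefore unknown, and the errors below describe variation along the genome and not between cultures. All positions are in hg19.

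The list held 23612 accessible regions, of which 23444 lay on chromosomes 1 to 22 and X. They covered 20.9 Mb in all, and those on chromosomes 1 to 22 and X covered 0.682% of the length of these chromosomes. The median region was 756 bp wide (95% bootstrap interval 750 to 762), with quartiles at 547 and 1082 bp. The median distance from a region to the next was 44.1 kb, no regions overlapped, and 0 lay on the mitochondrial genome. Each region carries the authors' score, which has the form of a scaled measure of reproducibility between replicates. It was at its cap of 1000 for 14180 regions (60.1%) and never under 541.

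High-scoring regions were wider. The median width was 953 bp at the score cap and 556 bp below it, a difference of 397 bp (two-sided permutation test, p = 0.0001, the smallest that 10000 permutations can give). Below the cap, width and score were related across regions, with a Spearman rho of 0.216 (95% bootstrap interval 0.195 to 0.235). Regions are not independent replicates, so this p describes the list and not the cultures. Because 14180 regions shared the highest score, the 3 regions to be named by score were taken by width among them. The widest on a chromosome spanned 5301 bp in band 21q21.3 (chromosome 21, 26948981 to 26954281). This band is known to hold MIR155HG, the host gene of a microRNA active in B cells, although no gene was assigned to the region here and this gene was singled out after the region was seen. The other 2 lay on unplaced sequences and were 28902 and 5973 bp wide.

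Among the light and dark Giemsa bands of the chromosomes, accessible regions were most frequent in light bands and least frequent in the darkest. Light bands are known to be gene-rich, but whether accessible regions follow gene density was not tested here. Light bands held 9.81 regions per Mb (95% bootstrap interval over bands, 9.41 to 10.2) and the darkest 5.89 (5.25 to 6.54). The bands of intermediate stain lay in order between them, at 8.16, 7.45 and 7.17 regions per Mb from pale to dark. Centromeric bands held 1.13 and variable heterochromatic bands 0.776 regions per Mb, and the stalks of the acrocentric chromosomes held 0. No region was listed in 27 of 46 centromeric, 12 of 16 variable and 5 of 5 stalk bands. Their length includes unsequenced stretches, where no region could be listed, so these values are not read as low accessibility.

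The light bands exceeded the darkest 1.67-fold (1.49 to 1.88; two-sided permutation test of stains among the bands of each chromosome, p = 1e-05, the smallest possible; adjusted p = 1.33e-05 over 4 comparisons). Light bands were denser on 18 of the 18 chromosomes that have both kinds. Against the palest of the dark bands the ratio was 1.203 (permutation p = 0.0002, adjusted p = 0.0002), with light bands denser on 15 of 22 chromosomes. Regions were also wider in light bands, where the median over bands was 767 bp, than in the darkest, where it was 659 bp (permutation test within chromosomes, p = 0.0001, the smallest possible). Pooled over regions, the median was 774 bp in light bands, 794 bp in the palest dark class and 680 bp in the darkest, so width did not peak in light bands. The difference of 108 bp between light and darkest bands fell to 62.5 bp among regions below the score cap (permutation p = 0.0001). The share of regions at the score cap lay between 59.0% and 60.2% in the 5 stain classes. Neighbouring bands are not independent, so these p-values may be too small.

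**Figure D1:**
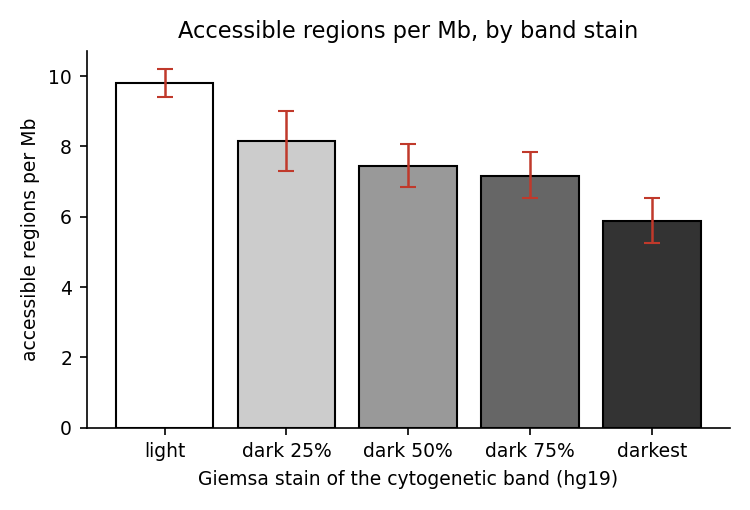
Accessible regions per Mb of cytogenetic band (y axis) for the 5 Giemsa stain classes (x axis, light to darkest). Bars are pooled densities and error bars are 95% bootstrap intervals over bands, falling from 9.81 in light to 5.89 in the darkest bands.

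Leaving out centromeric, variable and stalk bands, the densest band of at least 1 Mb was 6p12.2, with 38 regions or 34.5 per Mb, followed by 12q13.3 with 22.7 and 6p24.2 with 21 per Mb. The median over the 747 such bands was 8.28 per Mb, with quartiles at 5.44 and 11.38. In 6 of them no region was listed: 11p11.12, 2q37.2, 6p21.33, 6p21.32, Xq21.32 and 14q31.2. Band 11p11.12 lies in an interval across the centromere of chromosome 11, over which 10 region numbers were skipped. Removal of regions after numbering is therefore not excluded there. Bands 6p21.33 and 6p21.32 are known to hold class I and class II HLA genes, which encode antigen-presenting molecules. Both lie within a longer interval without regions, described below. Reads there that are shared with alternative haplotypes in the assembly may have been lost. The empty HLA bands are therefore not read as closed chromatin. The densest and the empty bands were chosen by rank after their values were seen.

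Outside centromeric, variable and stalk bands, chromosomes 22 and X carried the fewest accessible regions for their length, and chromosome 19 the most. Chromosome 22 held 4.40 regions per Mb (95% bootstrap interval over bands, 3.01 to 5.92), chromosome X 5.10 (3.97 to 6.27) and chromosome 19 10.4 (9.004 to 11.9). Chromosome 22 lay at 0.529 times the density of the others (two-sided permutation test of bands among chromosomes, p = 0.00038, adjusted p = 0.00437 over 23 chromosomes). Chromosome X lay at 0.604 times the others (permutation p = 1e-05, adjusted p = 0.00023). Bands of 1 chromosome are not independent of their neighbours. These p-values, and the others below from permuting bands among chromosomes, may therefore be too small.

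Densities on the remaining 21 chromosomes ran from 6.34 on chromosome 15 to the value on chromosome 19, and none of these chromosomes passed the adjusted test. The closest was chromosome 15, at 0.762 times the others (adjusted permutation p = 0.051), and chromosome 19, at 1.26 times, had an adjusted p of 0.231. The coefficient of variation of the density over 23 chromosomes was 19.2%, larger than in any of 10000 permutations of bands (p = 0.0001, the smallest possible). Without chromosomes 22 and X it was 14.5% (permutation p = 0.002). The planned relation to gene density was not run, since the gene table at hand is of another genome build.

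**Figure D2:**
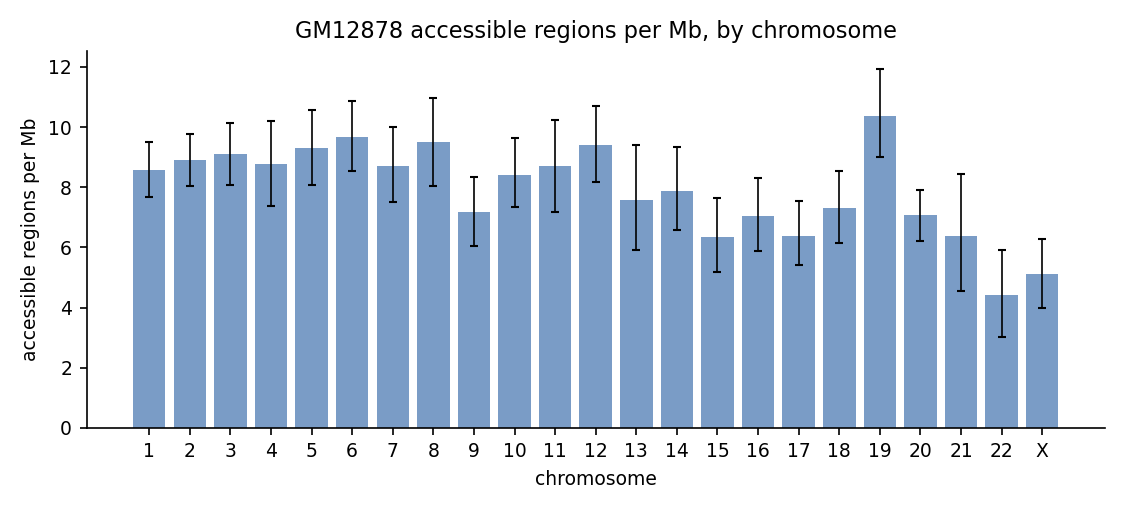
Accessible regions per Mb (y axis) on chromosomes 1 to 22 and X (x axis), without centromeric, variable and stalk bands. Bars are pooled densities and error bars are 95% bootstrap intervals over bands; chromosome 22, at 4.40, and chromosome X, at 5.10, are the lowest.

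Accessible regions lay in clusters far more often than randomly placed regions of the same widths. Joining regions that lay within the planned joining distance of each other gave 163 clusters of 5 or more regions, which held 949 regions. Random placement within the same chromosome gave 3.24 ± 1.52 such clusters (SD over 100 placements) and placement within the same band 7.51 ± 2.47. In neither did any placement reach the observed number (one-sided permutation p = 0.0099, the smallest possible). Of the regions, 41.9% had a neighbour within this distance, against 19.4% and 21.98% in the 2 kinds of placement, and 13628 regions (58.1%) stood alone. Promoters could not be told from distal sites, so all regions entered, where distal ones alone had been planned. The number of clusters depended on the joining distance, with 35 at 5 kb and 471 at 25 kb, and fell to 36 among regions at the score cap, above random placement each time (permutation p = 0.0099).

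The cluster with most regions held 14 over 67.5 kb in band 2p11.2 (chromosome 2, 85106552 to 85174082). A cluster of 12 lay in 3q11.2 (chromosome 3, 98240740 to 98287164) and 1 of 11 in 6p25.3 (chromosome 6, 291241 to 357702), the band known to hold IRF4, a transcription factor of activated B cells and plasma cells. A cluster of 10 lay in 1q31.2 (chromosome 1, 192475820 to 192529104), the band known to hold RGS13, a regulator of G-protein signalling in germinal centre B cells. With 9 regions each, clusters in 1p22.3, 12q24.33 and 13q32.2 tied for the fifth place, the first of them the shortest at 38.9 kb (chromosome 1, 85424922 to 85463800). The genes are named as background to the bands, were singled out after the clusters were seen, and were not assigned to them. A band holds many genes, and none was named for the clusters in 2p11.2 and 3q11.2. The names therefore show no B-cell theme among the clusters.

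**Figure D3:**
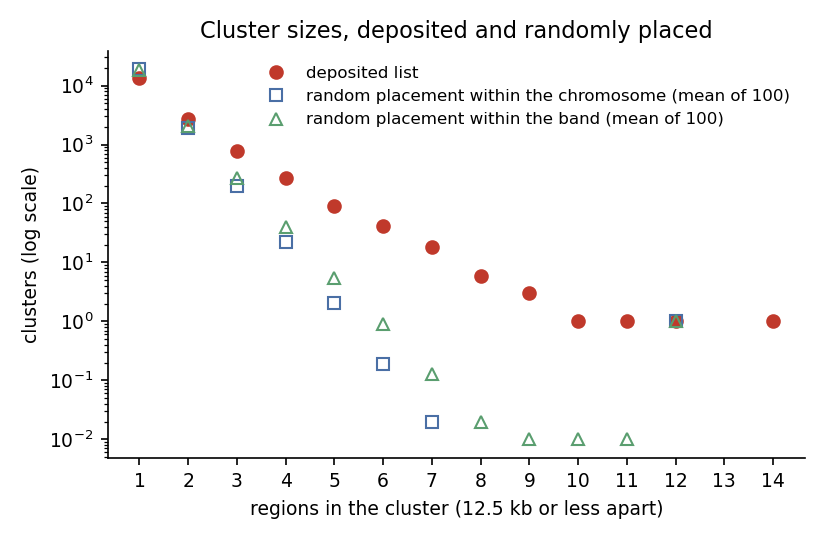
Number of clusters (y axis, log scale) by the number of regions in them (x axis), with regions joined when within the planned distance of each other. Filled circles are the deposited list and open symbols means of 100 random placements; the random point at 12 is the cluster in 3q11.2, whose regions kept their place because that band is classed as variable.

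The longest intervals with no region, outside centromeric, variable and stalk bands, were 6.04 Mb on chromosome 21, 5.17 Mb on chromosome 6, and 4.89 and 4.68 Mb on chromosome X. The interval on chromosome 21 (19297736 to 25340889) lay for 77.8% of its length in the darkest bands, and the longer one on chromosome X for 99.3%. The interval on chromosome 6 (28367914 to 33538525) lay for 0% in the darkest bands and for 60.7% in light or the palest dark bands. The shorter of the 2 on chromosome X also lay mostly outside the darkest bands, which made up 16.5% of it. The interval on chromosome 6 takes in the major histocompatibility complex. At the average of chromosome 6, 47.4 regions would lie across the complex, with its bounds rounded. On this chromosome, 10000 random windows of its length held a median of 50 (95% range 19 to 75). The windows left out the complex and centromeric bands, outside which the next longest interval without regions was 2.93 Mb. No window of 4.9 Mb could thus hold 0 regions. The one-sided random-window p of 0.0001 was therefore fixed by the choice of the interval and tests nothing. The interval on chromosome 6 was chosen after it was seen. Loss of reads shared with alternative haplotypes of the complex is a candidate explanation, taken up in the closing section. The interval is therefore not read as closed chromatin.

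**Figure D4:**
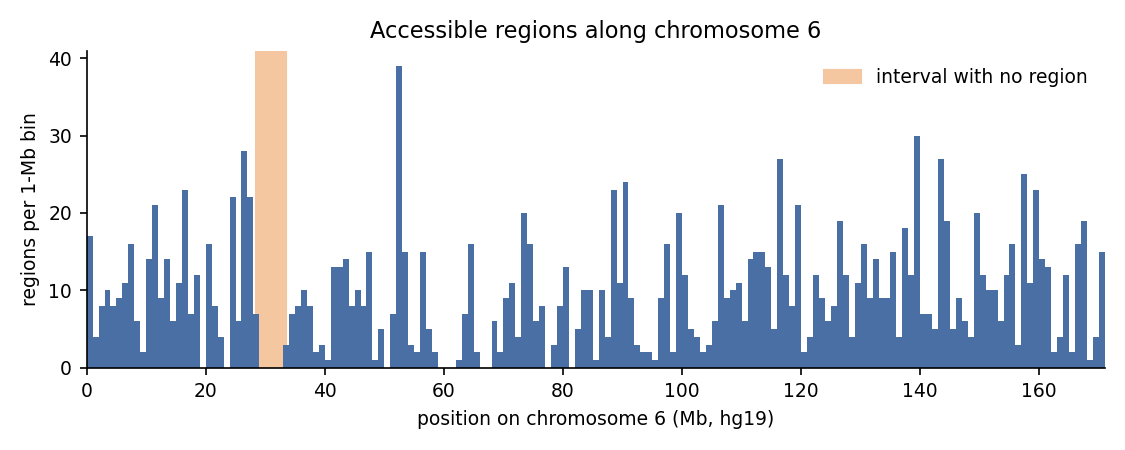
Accessible regions in 1-Mb bins (y axis) along chromosome 6 (x axis, Mb in hg19). The shaded interval of 5.17 Mb, from 28367914 to 33538525, holds 0 regions.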

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

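A signal lay outside the chromosomes on which the comparisons rest. On the unplaced sequences of hg19, 165 regions were listed, on 17 of the 59 such sequences, or 27.002 per Mb against 7.72 on chromosomes 1 to 22 and X. Of these regions 75.8% were at the score cap. The sequences Un_gl000225, 9_gl000199_random and Un_gl000216 held 44, 35 and 23 of them. Of the other 3 regions outside chromosomes 1 to 22 and X, 2 lay on haplotype sequences and 1 on chromosome Y. The widest region of the whole list, at 28902 bp, lay on Un_gl000220 (117446 to 146347), a sequence known to hold ribosomal DNA. No explanation was tested.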

How the results depend on the processing

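Of 32 alternatives over 9 results, 26 left the result the same, 6 moved the value and 0 reversed it. A tested result was the same if it kept its direction and side of the threshold. A count had to stay within 1.5 times, and the median width within its bootstrap interval (750 to 762 bp). The 5 planned ones were autosomes only, no chromosome 19 and the score cap for the density by chromosome, and 2 joining distances for clusters. Those for the density were run on its spread over chromosomes, which took the place of the planned correlation. The other 27 were chosen after seeing the data. Some settings could hardly change a result, since chromosome 19 has no darkest band and none of the 5 loci with a second copy lies on chromosome 22. The count of regions in these loci went from 3 to 2, at the limit of 1.5 times. The tally is therefore not a measure of robustness. With regions at the score cap only, the list held 14180 regions, of median width 953 bp, and 36 clusters; below the cap the median width was 556 bp. Joining at 5 kb gave 35 clusters and at 25 kb 471, by the construction of the setting. The light-to-darkest ratio ran from 1.61 on autosomes to 1.67, the chromosome 22 ratio from 0.380 over all bands to 0.657 below the score cap, and the chromosome X ratio from 0.579 to 0.635. The width difference between light and darkest bands ran from 62.5 to 111.5 bp. The coefficient of variation of density over chromosomes ran from 14.5% to 24.4%. The planned stricter subset by score could not be formed because of ties, so the cap stood in for it. No paired analysis was possible because the list has 1 group and no values per replicate, and no replicate could be left out. The alternatives for promoters, gene lists, distal regions, GC and CpG content, CpG share, motifs and widths of promoter and distal regions were not run, since no genes or sequence of hg19 were used here. Depth is unknown, so an interval without regions cannot be called closed chromatin.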

Other observations

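All tests in this part were chosen after the result was seen. The bands that hold the genes of 11 B-lineage transcription factors were compared with 18 bands that hold the genes of factors of muscle, liver, neurons, epithelia, fibroblasts, endothelium and stem cells, taken from gene lists fixed before the data were examined (for B cells, the identity and germinal centre lists). POU5F1, in the empty interval on chromosome 6, was left out. The hypothesis was that the B-lineage bands hold more regions per Mb. The densest of the bands compared was a non-blood one, that of OVOL1 (11q13.1), with 19.6 per Mb. The 2 densest B-lineage bands were those of PAX5 (9p13.2), which maintains B cell identity, and EBF1 (5q33.3), which specifies the lineage, each with 17.1 per Mb. The band of MEF2B (19p13.11) held 15.7, and that of XBP1 (22q12.1), a plasma cell factor, only 1.62. The median was 11.9 per Mb over B-lineage bands and 10.3 over the others, and the difference missed the threshold (two-sided permutation test, p = 0.0736). Without 4 B-lineage bands whose values had been seen before the comparison was set up, p was 0.147, and relative to the mean of each band's stain it was 0.269. Against random sets of bands, permutation p was 0.0241 for the 11 B-lineage bands, 0.0673 for the 7 whose values had not been seen first, and 0.0854 for the non-blood bands. The median of the 11 lay above the 95% range of random sets (5.32 to 11.6), and 10 of the 11 B-lineage and 12 of the 18 non-blood bands lay above the median of all bands. The median of the 7 was also 11.9 per Mb, but lay inside their wider random range (4.55 to 12.4). The B-lineage bands are not shown to differ from the non-blood bands, nor from random bands once those seen first are left out. A band holds many genes, so these values say nothing of single promoters.

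For the major histocompatibility complex, across which no region was listed, the values argue against a removal of regions after they were numbered, since 0 region numbers were skipped across the interval, and against a stretch of the darkest bands, which made up 0% of it. A candidate explanation is that reads shared with a second copy in the assembly were lost, since hg19 carries alternative haplotypes of the complex. The other 4 loci examined that have a second copy in hg19, on chromosomes 4, 17 and X, held 3 regions in 5.3 Mb. Random windows held a median of 31 (95% range 10 to 58). The one-sided random-window p was 0.0019, and 0.0071, 0.0034, 0.02 and 0.0034 with each locus left out. Taken singly, 1 of the 4 passed the threshold (one-sided permutation p = 0.036 at the tip of the short arm of chromosome X, and 0.086, 0.24 and 0.41 at the others), so the explanation rests on the pooled loci. At the tip of the long arm of chromosome X, removal after numbering is not excluded. Between the last region of this chromosome and the next sequence 42 numbers were skipped, against 0 at each of the other 3 loci. Without this tip the pooled one-sided random-window p was 0.0034. No biological explanation was tested.

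Chromosome 22 had few regions per Mb. Centromeric, variable and stalk bands do not account for it, since the ratio to the others without them was 0.529, nor does its stain make-up, with a ratio of 0.522 in light bands only. Removal of regions after numbering is argued against by 1 skipped number outside those bands, where 147 regions were listed and 294 would follow from the stains. The share of its regions at the score cap was also lower, at 50.3% against 59.98% elsewhere (permutation test over bands, p = 0.00324, adjusted p = 0.0373 over 23 chromosomes). A weaker signal along the chromosome is a candidate explanation. The score has the form of a measure of reproducibility, however, and the list holds no signal values. Few regions and low scores may be the same effect, so this share cannot decide the question. What would weaken the signal, such as GC content, was not tested, and no biological explanation was tested.

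Chromosome 17 had a low share at the score cap too, 51.4% against 60.1% elsewhere (permutation test, adjusted p = 0.00345). Its density, at 0.765 times the others, missed the threshold (permutation test, adjusted p = 0.084). Across 23 chromosomes, regions per Mb and the share at the cap rose together, with Pearson's r = 0.652 (permutation p = 0.00094) and Spearman's rho = 0.498 (permutation p = 0.0174), the 1 relation of this kind computed. Regions at the cap enter both measures, and permuting chromosomes does not allow for this. Part or all of the relation may therefore be built in. Without the 2 chromosomes farthest from the median density, 22 and X, r was 0.705 (permutation p = 0.00014), and it ran from 0.522 to 0.796 with 1 chromosome left out at a time. Chromosome X went against the relation, with few regions and 61.5% of them at the cap.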
